A study of Scophthalmus maximus with 18 samples.

How the data were processed

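Expression was measured in spleen, liver and head kidney of turbot on 18 single-colour arrays, per the labels 1 for each of 3 organs on day 0 (not injected) and on days 1, 3, 7, 15 and 25 after injection of the ciliate, each from RNA pooled over 5 fish. The 6 arrays of an organ shared 1 slide and each organ had a slide of its own. The control and days 1, 3 and 7 lay in the first row of the slide and days 15 and 25 in the second. Groups followed the labels, and no array was left out of the comparisons. Day entered the organ comparisons as a factor, which pairs the 3 organs by the day of sampling.

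The scanner files hold spot signals as intensity in linear units, per the file headers, made with Agilent Feature Extraction 9.5 by subtraction of a spatial background and detrending within the array, with no scaling between arrays. The spot flags in the same files are of other kinds, per the file headers, and mark spots well above background, saturated spots and outliers. The deposited value table holds intensity as well. Its values equal the processed signal of the scanner files to a relative deviation of at most 0.00018 when its entries are taken in spot order, with 25712 spots left empty. Of the empty spots 9472 were not well above background, 4190 had an outlier flag only and 12050 had neither, and the rule behind these is not stated. The complete probes of that table numbered 1698, so the scanner files were used, with the table as an alternative.

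Each array held 13580 spots apart from controls, 5 for each of 2716 probes. No probe had a gene annotation in the files. Processed signals were taken to log2, spots with an outlier flag were dropped (147 to 370 per array), the 75th percentile of the array was subtracted and the spots of a probe were averaged. A probe was well above background on an array when the majority of its spots were. Probes so measured on at least 3 of the 18 arrays were tested, which left 2673 and removed 43, and 2412 were well above background on all 18. The 10 brightest probes held 6.61% to 10.27% of the signal of an array, and 25 spots were saturated, all in liver. Where the dimmer side was not well above background on any array, a fold is given as a lower bound, computed against the lowest signal on the same array that was well above background.

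Comparisons used limma 3.58.1 in R 4.3.3, with lmFit and eBayes over all 18 arrays, two-sided, and Benjamini-Hochberg adjustment over the tested probes at 0.05. Organ differences, single days and late against early days came from a model with organ and day as factors, for which the 3 organs served as the only repeats of a day. Infection within an organ and its difference between organs came from a model with a control and an infected mean per organ, in which a single control array is assumed to vary like the infected arrays. Infection over the organs used organ as a factor and day as a random block, with a consensus correlation of 0.253. The value was 0.266 where day was tried as a block in the models by organ. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Single arrays were compared with the control array of their organ without a test, at a threshold of 2-fold. Probe sets were compared with 10000 random lists matched on mean signal.

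The fits were tested on simulated data with 2673 probes, of which 50 per fold size were changed. At 2-fold, organ differences were recovered for 92% to 94% of changed probes, infection within an organ for 42% in spleen, 50% in liver and 66% in head kidney, and single days for 70% to 82%. Differences in infection effect between organs were recovered for 8% to 16% at 2-fold and for 64% at 4-fold. Between 3 and 12 unchanged probes were called per comparison. The simulated noise was independent between arrays, with no difference between pools of fish shared by the organs of a day. These figures therefore do not cover calls that such differences would give.

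The comparisons, the tests, the filter, the thresholds and most of the alternatives were set before the data were examined. These alternatives were quantile normalization, median centring, normexp background correction with an offset of 50 together with quantile normalization, no filter, a filter on all 18 arrays, the deposited table, other sets of arrays or blocks in the fit, a 3-fold threshold, and leaving out each array, day or organ. Scaling on the E1A control spots, leaving out liver-high probes, leaving out 4 arrays and using only days 1, 3 and 7 were added after the data were seen. The rule for naming genes took the 10 largest rises and falls among annotated probes. Without annotation it gave none, and the 2 largest called changes in each direction per comparison were named in its place, a choice made after the files were read. Other probes, chosen after their values were seen, are R1__1529, R1__1534, R1__1389, R1__479 and R1__1031, and R1__715 in liver. The lists of immune genes and cell type markers and their set tests were left out, since no probe could be assigned to a gene.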

Results

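The expression of immune-related transcripts was measured in turbot (Scophthalmus maximus), a farmed flatfish, before and after injection of Philasterides dicentrarchi, a ciliate that invades the body cavity and organs of fish. The question was how spleen, liver and head kidney, the last being the main blood-forming organ of bony fish, respond along the course of the infection. Fish received 0.1 mL of a suspension of parasites into the body cavity, and groups of 5 fish were taken on days 1, 3, 7, 15 and 25. A further 5 fish, not injected, were taken on day 0 as the only control. The labels name no group injected without parasites and no control of a later day. Effects of the injection itself and of time cannot be told apart from those of the parasite, also where infection is named below. Each organ was pooled over the 5 fish of a day, which gave 18 single-colour arrays, 6 per organ and 1 for each organ and day. The labels name no replicate pools, so no organ and day had a replicate. The p-values below therefore rest on the spread among arrays of different days or organs. Where days are compared over the organs, the 3 organs of a day come from the same fish, so these p-values do not cover differences between pools of fish. Each array carried 2716 probes of 54 to 60 bases in 5 spots each. Between 2539 and 2650 probes per array were well above background, the 75th percentile of the signal ran from 5790.2 to 14189.5 intensity units, and the median coefficient of variation among the spots of a probe was 3.66% to 5.29%. The number of arrays limited the precision. The files do not pair the probes with genes, so probes are given by their identifiers with the sequence of those described first, and the preset lists of immune genes and cell type markers could not be applied. Groups of probes are instead described by the organs in which their signal was high. Signals are log2 values relative to the 75th percentile of their array.

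The 3 organs were compared over all 6 days to find the transcripts typical of each. Most probes differed between liver and the other organs. In spleen, 1500 probes were higher and 775 lower than in liver by limma with Benjamini-Hochberg adjustment over 2673 probes, and 242 of the lower probes were at least 16-fold lower. Head kidney had 1512 probes higher and 749 lower than liver, with 232 at least 16-fold lower. Spleen and head kidney were closer to each other, with 986 probes higher and 711 lower in spleen and 39 and 76 of them at least 16-fold apart. The median absolute log2 difference was 1.15 between spleen and liver, 1.07 between head kidney and liver and 0.44 between spleen and head kidney. Scaling decided how the calls divided by direction. Centring each array on its median gave 1145 probes higher and 1089 lower in spleen than in liver, and scaling on the E1A control spots gave 1919 and 470. For head kidney against liver the divisions were 1053 to 1129 and 2117 to 366, and for spleen against head kidney 1047 to 659 and 351 to 938. Each organ was hybridised on a slide of its own, so organ and slide cannot be told apart in these counts.

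Probe R1__3402 (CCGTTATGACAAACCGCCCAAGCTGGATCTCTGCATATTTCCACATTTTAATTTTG) stood at 1.58 ± 0.37 in spleen and -7.55 ± 0.33 in liver (SD, n = 6 arrays each), a log2 difference of 9.13 (SE 0.22, limma adjusted p = 1.83e-12), and was well above background on 4 of the 6 liver arrays. Probe R1__1872 was lower in spleen, with -7.35 ± 1.45 against 1.90 ± 0.31 in liver (log2 difference -9.25, SE 0.57, limma adjusted p = 4.76e-09). It was well above background on only 3 of the 6 spleen arrays. R1__490 marked the head kidney. It stood at 3.68 ± 0.27 there, 11.71 log2 units above liver (SE 0.48, limma adjusted p = 1.06e-10), with a log2 difference of -11.52 for spleen against head kidney, and was well above background on only 2 of 6 liver and 3 of 6 spleen arrays. R1__2841 was not well above background on any liver array and was at least 786-fold higher in head kidney (limma adjusted p = 1.72e-13), where the dim side is bounded by the lowest signal well above background. Probes R1__246 and R1__715 were bright in spleen, at 3.87 ± 0.51 and 3.34 ± 0.52, and stood at -7.60 ± 2.48 and -7.92 ± 2.39 in head kidney, where they were well above background on 3 of 6 arrays (limma adjusted p = 1.19e-07 and 4.83e-07). For all probes dim in part of an organ, R1__3402, R1__1872, R1__490, R1__246 and R1__715, the size of the difference is uncertain. The wide spread of R1__246 and R1__715 in head kidney came from the days. Both lay between -9.46 and -10.50 on the control and on days 1 and 3, at -5.12 and -5.86 on day 7, and at -4.63 and -4.78 on day 25.

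The 5 infected arrays per organ against its single control addressed the response to infection in each organ. In the main settings very few probes differed by this test. It compares the mean of the 5 infected arrays with 1 control array and counts change between days as spread. With a single control array its power was limited. More probes were called in head kidney under some other settings, given below. In head kidney 2 probes fell, and both were lower on all 5 days. R1__2950 (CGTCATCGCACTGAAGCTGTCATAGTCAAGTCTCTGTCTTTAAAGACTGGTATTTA) stood at -4.15 ± 0.19 (SD, n = 5) in infected head kidney against -0.66 in the control, a log2 change of -3.48 (SE 0.27, limma adjusted p = 5.39e-06). R1__1326 (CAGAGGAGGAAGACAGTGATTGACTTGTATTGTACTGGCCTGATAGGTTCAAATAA) stood at -3.80 ± 0.26 against -0.55, a log2 change of -3.25 (SE 0.50, limma adjusted p = 0.0177). In liver 1 probe rose, R1__66, which was not well above background in the control and at least 1.1-fold higher on the infected arrays (log2 change 1.18, SE 0.17, limma adjusted p = 0.0215). No probe passed in spleen, where limma gave 148 probes at an unadjusted p under 0.05 and a lowest adjusted p of 0.276. Liver and head kidney had 288 and 186 such probes. Over the 3 organs together limma called 0 probes, with 281 at an unadjusted p under 0.05 and a lowest adjusted p of 0.288. Singling out 1 infected array against the other 5 of its organ called as many or more probes in some cases, 150, 13 and 26 for liver on days 1, 15 and 25, 5 for spleen on day 7 and 125 for head kidney on day 25. Without liver-high probes, which are those at least 16-fold higher in the liver control than in both other controls, limma called 168, 15 and 31 for these liver days, 5 for spleen on day 7 and 0 for head kidney on day 25, with 32 at an unadjusted p under 0.05 there. The liver count depended on single arrays and settings, being 50 without the day 15 array and 0 when only the 6 liver arrays were fitted. With only days 1, 3 and 7, limma called 13 probes in spleen, 10 in liver, 8 in head kidney and 9 over the organs.

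Whether the change from control differed between organs was tested as an interaction. R1__2950 was the only probe called, for spleen against head kidney, where the changes from control differed by 3.62 log2 units (SE 0.37, limma adjusted p = 0.000297). Its signal in spleen was already low in the control, at -4.66, and stayed between -4.89 and -4.13 on the infected days, while liver went from -1.50 in the control to between -3.20 and -2.51. Limma called 0 probes for spleen against liver and 0 for head kidney against liver, with 87 and 131 at an unadjusted p under 0.05 against 51 for spleen against head kidney. Apart from R1__2950 in spleen and head kidney, probes that pass the test in one organ and not in another are therefore not shown to differ between them. The call of R1__2950 rests on the single head kidney control array, at -0.66, so a deviation of that array alone would give it. The same holds for the call of R1__1326 in head kidney.

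**Figure D1:**
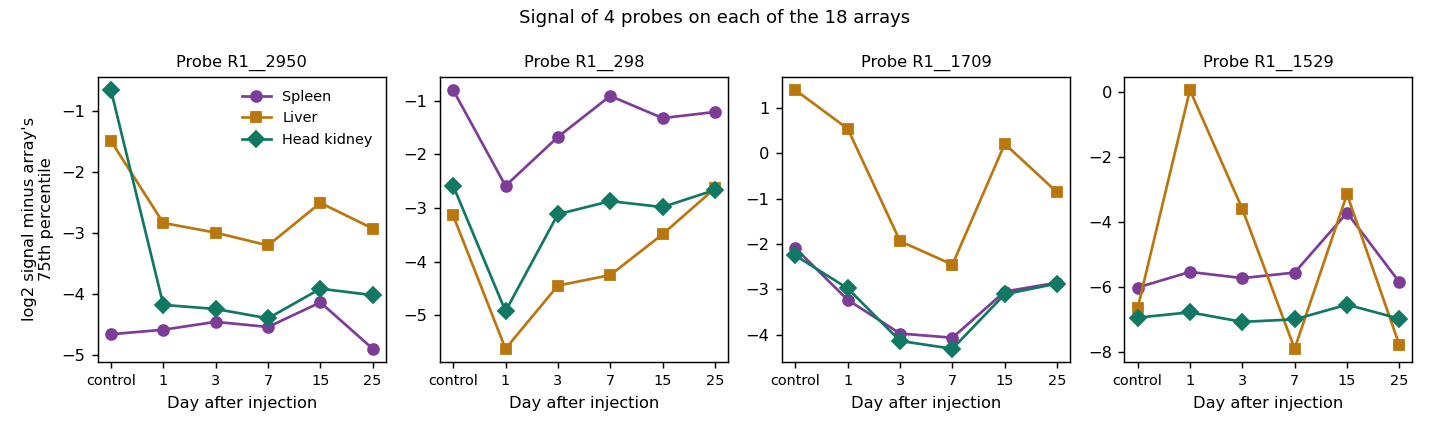
Signal of 4 probes on the 18 arrays, as log2 intensity relative to the 75th percentile of the array (vertical axis, a separate scale per probe) by day (horizontal axis, unevenly spaced days drawn at equal distance), with 1 array per point and no error bars. R1__2950 fell from -0.66 in the head kidney control to -4.18 on day 1, R1__298 was lowest on day 1 in all 3 organs, R1__1709 was lowest on day 7 in all 3, and R1__1529 stood at 0.05 on the liver day 1 array.

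Comparing each day with the control over the 3 organs gave the most calls on day 7 and few or none on the late days. On day 1, 55 probes rose and 66 fell by limma with Benjamini-Hochberg adjustment, and on day 3 the numbers were 113 and 188. Day 7 had 256 higher and 226 lower. On day 15 only 8 rose and 1 fell, and on day 25 limma called 0 probes, with 412 at an unadjusted p under 0.05. Changes were moderate, with a median size among called probes of 1.77-fold on day 1, 1.6-fold on day 3 and 1.55-fold on day 7. A difference of the pool of fish of a day from the control pool cannot be told apart from an effect of the day. The counts rested on the spread shared by all 18 arrays and on spleen and head kidney. Without spleen they were 1, 0 and 0 on days 1, 3 and 7, without head kidney 0, 1 and 0, and without liver 258, 513 and 550. A fit of only the 6 arrays compared called 0 probes on each of these days and on day 15. Scaling on the E1A control spots left 11, 0 and 1 (8 higher and 3 lower on day 1). Leaving out the 4 spleen and head kidney arrays with the highest correlation with liver arrays, spleen on days 1, 3 and 7 and head kidney on day 25, left 42, 7 and 4.

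**Figure D2:**
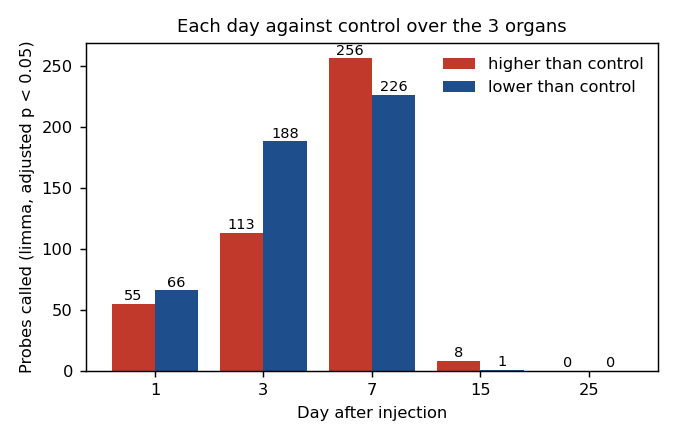
Number of probes called by limma at a Benjamini-Hochberg adjusted p under 0.05 (vertical axis) for each day after injection against the control over the 3 organs (horizontal axis), with bars for probes higher and lower than the control. The bars grow from 55 and 66 on day 1 to 256 and 226 on day 7, and stand at 8 and 1 on day 15 and at 0 on day 25.

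The probes called and named for a day changed by up to 6.15-fold over the organs. R1__298 fell by 2.20 on the log2 scale on day 1 (SE 0.29, limma adjusted p = 0.00246), with -2.48 as the strongest change and -1.78 as the weakest among the 3 organs, and R1__348 fell by 1.89 (SE 0.28, limma adjusted p = 0.0036). R1__794 (SE 0.46) and R1__610 (SE 0.50), the latter far brighter in liver than in the other organs, rose 4.72-fold and 4.75-fold on that day (limma adjusted p = 0.0193 and 0.0272). R1__794 was back at -1.68 in spleen on day 3 after 1.38 on day 1 and -1.28 in the control. R1__1709 fell by 2.36 on day 3 (SE 0.38, limma adjusted p = 0.00718) and by 2.62 on day 7 (SE 0.38, limma adjusted p = 0.00429), in all 3 organs. R1__944 fell by 1.67 on day 3 (SE 0.39, limma adjusted p = 0.0248). The 2 largest rises among the called probes of day 3 were likewise of probes bright in liver, R1__858 with 4.10-fold and R1__2233 with 2.88-fold (limma adjusted p = 0.0489 and 0.0182). In liver they changed by only 0.44 and 0.09 log2 units. Without the 4 arrays named above their log2 changes went from 2.04 and 1.52 to 1.65 and 1.35, and with fewer arrays for the spread neither passed (limma adjusted p = 0.105 for both, 0.0198 to 0.275 and 0.00443 to 0.253 over the alternatives). On day 7, R1__114 rose 3.57-fold (SE 0.34, limma adjusted p = 0.00774), between 1.67 and 2.14 log2 units in each organ, while R1__2676 fell by 2.09 (SE 0.62, limma adjusted p = 0.0371). R1__1991 also rose on day 7 (limma adjusted p = 0.00766), by an uncertain amount. Its liver control was not well above background, its rise in liver was at least 2.46-fold, and its log2 change over the organs was 1.81, or 0.83 with normexp background and quantile normalization. On day 15, R1__1887 rose 2.44-fold and R1__252 fell by 0.67 on the log2 scale (limma adjusted p = 0.0466 for both), and neither passed without any one of the organs. Of all the probes named here for a day, only R1__298 and R1__348 passed without the 4 arrays. There the log2 changes were 2.07 and 1.98 for R1__794 and R1__610 on day 1, -2.50 and -1.84 for R1__1709 and R1__944 on day 3, 2.07, 1.95, -2.84 and -1.59 for R1__114, R1__1991, R1__1709 and R1__2676 on day 7, and 1.29 and -0.67 for the 2 probes of day 15.

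Late days, 15 and 25, were set against early days, 1 and 3, to find transcripts that changed during the infection without the control as the reference. Limma called 42 probes, 20 higher and 22 lower late. R1__3052 was 1.73 log2 units higher late than early (SE 0.17, limma adjusted p = 0.000334), with 1.42 as the smallest and 2.24 as the largest difference among organs, and R1__298 was 1.34 higher (SE 0.21, limma adjusted p = 0.0054). R1__294 was 2.08 log2 units lower (log2 difference -2.08, SE 0.29, limma adjusted p = 0.00329) and R1__2227 had a log2 difference of -1.68 (SE 0.30, limma adjusted p = 0.0159). R1__294 and R1__2227 stood at -4.70 and -4.20 on the liver day 25 array, against -1.25 and -1.02 in the liver control. For 40 of the 42 probes the late days lay nearer the control than the early days did. The division by direction was 17 higher and 51 lower with quantile normalization, 11 and 26 with median centring and 4 and 11 with scaling on the E1A spots. No probe was called without spleen or without head kidney, 29 were called without liver and 20 without the same 4 arrays. A fit of only the arrays compared also called fewer than the 42.

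The size of the response on each array was described by the probes at least 2-fold from the control of the same organ, with no test since each value rests on 1 array. Liver had 275, 316 and 358 such probes on days 1, 3 and 7, then 178 on day 15 and 288 on day 25. On day 15 the liver changes were nearly all upward, with 166 higher and 12 lower. Spleen had 233 on days 1 and 3 and 207 on day 7, and 69 and 42 on days 15 and 25. Head kidney had between 122 and 212 on every day. Without liver-high probes the numbers on days 1, 3, 7, 15 and 25 were 244, 293, 335, 174 and 275 in liver, 110, 93, 137, 54 and 32 in spleen and 134, 123, 125, 63 and 59 in head kidney. Few probes differed on every day in liver and spleen, and since the 5 days share 1 control array per organ, a deviation of that array would give the same picture. In liver 1 probe was at least 2-fold higher and 2 at least 2-fold lower on all 5 days, in spleen 3 and 6, and in head kidney 33 and 13. Without liver-high probes the head kidney numbers were 2 and 13.

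**Figure D3:**
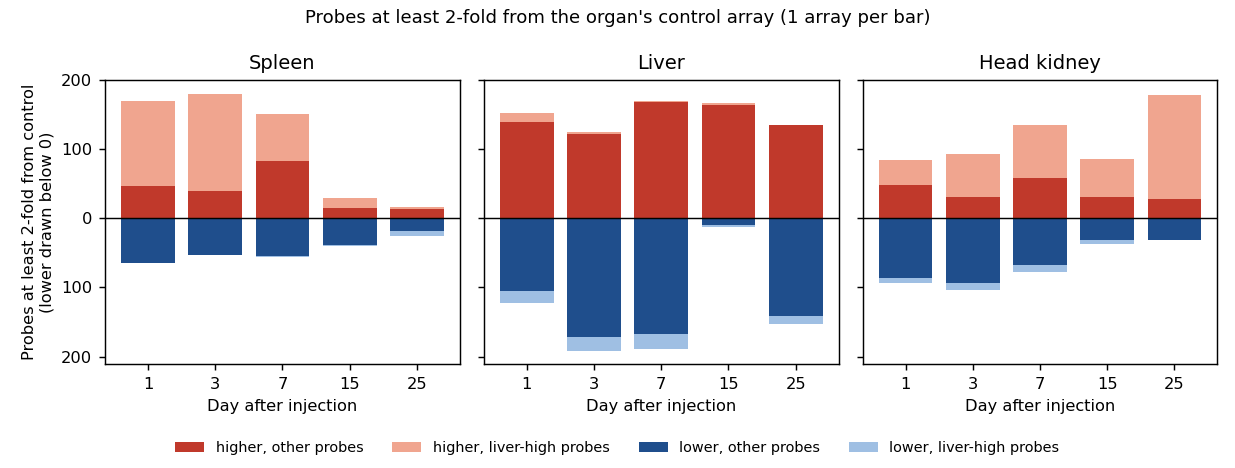
Number of probes at least 2-fold from the control array of the same organ (vertical axis, higher above and lower below the zero line) on each day (horizontal axis), with 1 array per bar and no error. Pale segments are the liver-high probes, which make up 140 of the 180 higher probes in spleen on day 3 and 150 of the 178 in head kidney on day 25.

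Liver had large single changes on day 1. R1__1529 (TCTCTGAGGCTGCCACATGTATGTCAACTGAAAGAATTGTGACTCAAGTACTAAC) was 105-fold higher than in the liver control, and R1__1534 was 37.1-fold higher. On day 3 they were 8.35-fold and 20.3-fold higher, and R1__1529 was again 11.4-fold higher on day 15. In liver R1__1389 was 14.2-fold lower on day 1 and R1__1709 was 10.0-fold lower on day 3 and 14.3-fold lower on day 7, while R1__715 was 17.9-fold lower on day 25. In spleen R1__2676 was lower on all days, by 10.7-fold on day 3, with a mean log2 change of -2.55 ± 0.80 (SD, n = 5 days). R1__479, not well above background in the spleen control, was at least 3.71-fold higher on day 25.

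Probes high in the control array of 1 or 2 organs changed as groups. Liver-high probes, defined after the correlations between arrays were seen, numbered 193. In spleen their median was 3.12-fold above the control on day 1, 4.96-fold on day 3 and 1.75-fold on day 7, and 0.905-fold on day 25. In head kidney it was 1.21-fold to 1.77-fold on days 1 to 15 and 14.8-fold on day 25, or 10.4-fold with the dim signals held at the lowest signal well above background. On day 25, 150 of the 178 probes at least 2-fold higher in head kidney were liver-high. R1__1031, also liver-high and not well above background in the control, was at least 173-fold higher. Liver RNA in the samples may be the source of the rises in spleen and on day 25 in head kidney, and was not separated from induction within the organs. The mean correlation of the array with the liver arrays, across probes, was 0.633 on day 25 against 0.368 for the head kidney control, and 0.632 for spleen on day 3 against 0.496 for the spleen control. Without liver-high probes these gaps were far smaller, 0.733 against 0.68 in head kidney and 0.737 against 0.705 in spleen. Probes are not independent replicates in these correlations.

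A set of 31 probes was at least 16-fold higher in both the liver and the spleen control than in the head kidney control, and was likewise defined after the control arrays were seen. R1__246 and R1__715 belonged to it. In liver its median was 3.75-fold below the control on day 3, 3.26-fold below on day 7 and 3.92-fold below on day 25, with 28, 25 and 28 of the 31 probes at least 2-fold lower, and 1.40-fold and 1.27-fold below on days 1 and 15. In head kidney the median of the 29 probes measured was 9.95-fold above the control on day 7, 4.39-fold on day 15 and 23.3-fold on day 25, and 5.85-fold, 2.78-fold and 13.8-fold with dim signals held at the lowest signal well above background. The day 25 rise was on the array where liver-high probes also rose 14.8-fold, and was not separated from that rise. In spleen it was 1.93-fold above the control on day 7. The liver medians of all 5 days lay below those of all 10000 random lists of probes matched on signal. Picking a set on the control arrays draws its changes toward the other organs through noise in those arrays, equally on all days. The random lists were not picked in that way, so the comparison with them does not allow for this pull.

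**Figure D4:**
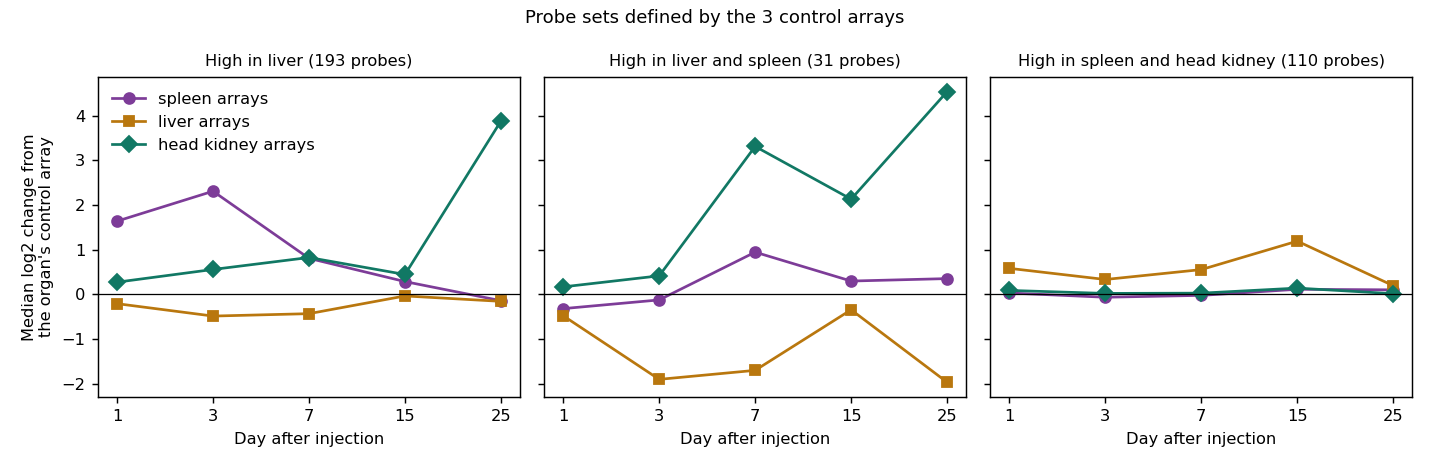
Median log2 change from the control array of the same organ (vertical axis) by day (horizontal axis, drawn at equal distance) for probes high in the control of liver (193 probes), of liver and spleen (31 probes) and of spleen and head kidney (110 probes), with 1 array per point and no error bars. Liver-high probes stood at 3.89 in head kidney on day 25, liver and spleen probes at -1.91, -1.71 and -1.97 in liver on days 3, 7 and 25, and spleen and head kidney probes at 1.19 in liver on day 15.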

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

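The tests of liver RNA in the spleen samples, in the form given here, were chosen after the result was seen. Across 56 groups of 5 or 6 arrays, 6 had an array further from the rest than Dixon's test allows at the 95% level, where chance alone gives about 1 in 20 groups. The array concerned was head kidney on day 25 in 5 of the groups, which share much of their data, and spleen on day 7 in the other.

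The median change of the liver-high probes over the 5 infected head kidney arrays had a gap of 0.847 of its range, set by 3.89 on day 25 against 0.27 to 0.83 on the other days. The mean correlation with the other head kidney arrays had a gap of 0.705 (0.916 on day 25 against 0.959 to 0.977), and the correlation with liver arrays a gap of 0.672 (0.633 against 0.368 to 0.455). Probe R1__2537, at -3.64 on day 25 and -9.73 to -8.07 on the others, had a gap of 0.728. Probe R1__190, at -1.49 against -9.43 to -6.67, had a gap of 0.653.

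Liver-high probes were raised in head kidney on day 25 and in spleen on days 1, 3 and 7, the 4 arrays of these organs most correlated with liver, and liver RNA in these samples may be the source. No test was set for head kidney on days 3, 7 and 15, where 33.7%, 42% and 30.6% were raised at least 2-fold. The log2 shares of the same-day liver level had robust SDs of 1.552, 1.66 and 1.806 there. These values lie beyond the bounds of 60% and 1.5 set against liver RNA for the other arrays. In head kidney 79.3% of the 193 probes were at least 2-fold above the control and the robust SD of their shares was 1.117 log2 units, which missed the preset bounds of 80% and 1. On spleen days 1 and 3 the robust SDs of 0.901 and 0.676 met the bound of 1. The lowest percentage was 63.7%, under the bound of 80%. A single share was taken as the median over alternate probes of the array and applied to the others. It would raise 59.1% and 72.5% of the probes on these spleen days, against 80.8% in head kidney. Since it is fitted to the same rises, it does not explain the missed bound. Of the probes a single share would raise, 148 of 156 were raised in head kidney, and 103 of 114 and 133 of 140 on spleen days 1 and 3. Of the remaining probes 5 of 37, 20 of 79 and 7 of 53 were raised. The share came from the rises of these same probes, so the counts cannot tell liver RNA from induction. With values between the bounds set for and against it, liver RNA stays open for these 3 arrays. The test was first set for the 3 spleen days together. On day 7, 36.8% were raised and the robust SD was 1.716. Under 60% or over 1.5 had been set as the outcome against liver RNA, so in that form the test went against it. A single share as small as 0.286%, fitted to the same probes, would raise only 29% there and leaves the shares of dim probes to noise. The robust SD about the rise it predicts was 0.612 against 0.465 to 0.706 on the other 3 arrays. That comparison was not part of the written bounds, and only with it does liver RNA stay open on day 7. Induction within the organs, a biological explanation, stays open on all 4 arrays. The outcome set for it, a slope of the rise on the liver level under 0.5 on at least 1 array, was met (lowest 0.108, spleen day 7). That outcome could not separate induction from liver RNA, since the fitted single share also gives slopes under 0.5, of 0.491, 0.112, 0.147 and 0.075. The measured slopes were 0.511, 0.23, 0.303 and 0.108, each higher than that of the fitted share. This reading of the slopes was not part of the written bounds.

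Probe R1__2958 over the 6 spleen arrays had a gap of 0.862, with -6.21 on day 7 and -9.99 to -9.47 on the others. It was well above background on only 1 of the 6 spleen arrays, so the size of the gap is uncertain. The infection effect on R1__2950 differed between spleen and head kidney by 3.62 log2 units by the limma interaction test (adjusted p = 0.000297), with a change of -3.48 in head kidney and 0.14 in spleen.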

How the results depend on the processing

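Scaling on the E1A spots, leaving out liver-high probes, only days 1, 3 and 7, and leaving out the 4 arrays nearest to liver (spleen days 1, 3 and 7, head kidney day 25) were chosen after the data were seen. Of 440 values of named probes under alternatives, 342 kept direction and side of the threshold, 98 kept direction but no longer passed, and 0 reversed. The losses did not fall on the probes named for organ differences, which make up part of the 342. The probes named for day 1 no longer passed without spleen, without head kidney or with only the arrays compared. R1__2950 passed in head kidney and in the interaction, and R1__1326 in head kidney (adjusted p 0.00235 to 0.0469), under every alternative that measured them. R1__66 in liver had an adjusted p of 0.00305 to 0.95. All alternatives for these probes keep the single control array of the organ. They therefore cannot tell the calls from a deviation of that array. Where no cause is given below, the cause was not tested.

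With the deposited value table, which has fewer complete probes, organ differences were 1441 for spleen against liver, 1403 for head kidney against liver and 1005 for spleen against head kidney, infection called 0 in liver and 0 in head kidney, the interaction of spleen and head kidney 0, and day 15 called 4. R1__2950 and R1__1326 are not complete there. Probes 2-fold from control every day numbered 1 in liver and 21 in head kidney. Normexp together with quantile normalization gave 1 call in spleen, 0 in liver, 18 in head kidney, 1 for the head kidney and liver interaction, 17 on day 25, 71 late against early and 26 every-day probes in head kidney. Quantile normalization alone gave 0 in liver, 1 for that interaction, 0 on day 15, 9 on day 25 and 68 late against early. Day as a random block gave 2 for it. Median centring gave 0 on day 15 and 5 every-day probes in liver. Only probes well above background on all 18 arrays gave 0 for infection in liver, 0 on day 15, and 1 and 30 every-day probes in liver and head kidney. A 3-fold threshold, stricter by construction, left 0 in spleen, 0 in liver and 18 in head kidney, and leaving out liver-high probes left 15 in head kidney.

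Scaling on the E1A spots gave 0 in liver, 11 on day 1, 0 on day 3, 1 on day 7, 1 on day 15 and 15 late against early. It moved the median log2 difference of all probes from 0.51 to 1.28 for spleen against liver, from 0.48 to 1.64 for head kidney against liver, from 0.11 to -0.28 for spleen against head kidney, from -0.02 to 0.46 for infection in liver and to 0.24 to 0.33 on days 1 to 15. Only the 6 arrays of the organ gave 0 in liver, and only the arrays compared, with fewer arrays for the spread, gave 0 on days 1, 3, 7 and 15 and 7 late against early. Only days 1, 3 and 7 gave 13 in spleen, 10 in liver, 8 in head kidney and 9 over the organs. Leaving out the 4 arrays gave 0 in liver, 11 in head kidney, 42 on day 1, 7 on day 3, 4 on day 7, 0 on day 15 and 20 late against early.

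Leaving out 1 day at a time gave 2212 to 2261 for spleen against liver, 2202 to 2257 for head kidney against liver and 1476 to 1613 for spleen against head kidney. Leaving out 1 infected array or day gave 0 in spleen, 1 to 50 in liver (50 without day 15), 2 to 4 in head kidney (4 without day 25), 0 to 1 over the organs, 0, 0 to 2 and 1 to 2 for the interactions of spleen and liver, head kidney and liver, and spleen and head kidney. Leaving out 1 organ gave 0 to 258 on day 1, 0 to 513 on day 3, 0 to 550 on day 7, 0 to 1 on day 15, 0 on day 25 and 0 to 29 late against early, the highest without liver except on day 25. Slide and scan as blocks were not run, being the same as organ. Gene list tests were not run. Signal over background limits folds against dim arrays, given as lower bounds.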

Other observations

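The sets of probes high in several organs, the test on the liver day 15 sample, the splits for infection over the organs and the splits by whole days were chosen after the result was seen. A set of 110 probes was at least 16-fold higher in both the spleen and the head kidney control than in the liver control. In liver on day 15 its median was 2.28-fold above the control, with 71 of the 104 probes measured at least 2-fold higher and 100 higher at all, against 1.5-fold, 1.26-fold and 1.47-fold on days 1, 3 and 7 and 1.14-fold on day 25. Of the 104, 19 were not well above background in the liver control. With dim signals held at the lowest signal well above background, the medians were 2.21-fold on day 15 and 1.05-fold on day 25. Choice of the set by its low liver control draws its liver changes up on every day. In spleen and head kidney its median lay within 0.14 log2 units of the control on every day. The 37 probes high in the head kidney control were 1.60-fold, 1.73-fold, 1.54-fold, 1.63-fold and 1.30-fold below it in head kidney on days 1 to 25, though their choice by that same control array draws them down.

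Changes from control averaged over the infected days correlated across 2673 probes with r = 0.553 between spleen and head kidney, 0.255 between spleen and liver and 0.073 between head kidney and liver. Without liver-high probes the values were 0.402, 0.387 and 0.226 over 2480 probes. Probes are not independent replicates, and the 3 organs of a day share their fish per the labels.

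A larger share of tissue common to spleen and head kidney in the liver day 15 sample is a candidate explanation for its 71 raised probes. A single share of 2.80% of the spleen signal would raise 67 probes, of which 49 were raised, and 3.22% of the head kidney signal would raise 55, of which 37 were raised. Both shares were fitted to the same probes on the same array, so these counts decide nothing. The shares of single probes had a robust SD of up to 1.186 log2 units, between the bounds of 1 and 1.5, so the test left this open. No cell type could be examined, since the probes carry no gene names.

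Late days lay in the other slide row from the control and the early days. Had the row set the late against early calls, late arrays would differ from the control by as much as from the early arrays, a ratio near 1. The median ratio over the 42 called probes was -0.115 (quartiles -0.389 and 0.32), which argues against the row as the cause. Relative to the control, the median of the probes called higher late was -0.90 early and -0.20 late, and that of the probes called lower late 0.69 early and -0.20 late.

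Other splits of the arrays were counted for each comparison of groups of 3 or more. For the organ differences, fitted on the 12 arrays of the pair, 1 of 100 splits, the real one, gave as many calls, with 2224 against a highest other of 1610 for spleen and liver, 2207 against 1471 for head kidney and liver and 1920 against 1181 for spleen and head kidney, so chance can be excluded. Late against early days gave 8 calls with the days merged, against a highest other of 1 over 100 splits of single arrays. The 3 organs of a day share their fish, however, and whole days give only 3 splits, too few for a share under 0.05, with a highest other of 6. Infection over the organs called 0 probes by limma, with 281 at an unadjusted p under 0.05, so all 100 splits gave as many whatever the arrays, and this count decides nothing about chance. The highest other called 145, and what set its arrays apart was not tested. For single days there are only 10 splits, too few for a share under 0.05. The real values were 121, 301, 482, 9 and 0 on days 1 to 25, with a highest other of 0 on each day.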
